A study of Mus musculus with 30 samples.

How the data were processed

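RNA sequencing data of 30 libraries were used: 16 from kidney and 14 from retina of 21 mice, 9 of which gave both organs. Per the labels, organs were flash frozen, RNA was isolated with Trizol and libraries were sequenced on a BGISEQ-500. Age (16 weeks) is given for the whole study. The labels give tissue, diabetic status and genotype of each sample, and the animal number, which names the libraries with K for kidney and R for retina, was read from the sample name. Sex, strain background, litters and the hour of collection were not given in the sources used here.

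Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and quantified with kallisto (listed as version 0.4.6) on GRCm38.p6. The deposited tables give the authors' expected counts per gene, and the authors' TPM per gene, for 55385 genes in each library. Of the expected counts, 35% were not whole numbers, as reads shared by several transcripts are divided between them. They were rounded to whole numbers before testing. Totals per library ran from 19870485 to 22643055 counts over both organs. At a TPM of at least 1 there were 12506 to 14724 genes in kidney libraries and 18460 to 19320 in retina libraries. Coordinates and gene types came from GENCODE M21. Of the gene identifiers, 54487 matched with their version, 55144 without it, and 241 did not match. No column was without a sample, and no 2 libraries were duplicates.

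The main analysis used edgeR 4.0.16 in R 4.3.3, one fit per organ with its 4 groups. Counts were normalised by the trimmed mean of M values, genes were kept by filterByExpr (18177 in kidney, 20979 in retina), and quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method, with a call at an adjusted p under 0.05. Each organ had 5 comparisons: diabetic minus non-diabetic within each genotype, knockout minus wild-type within each diabetic state, and the genotype by diabetes interaction, which is the diabetes effect in the knockout minus that in the wild-type. These groupings, comparisons and the first set of other settings were fixed before the data were examined. CPM values used normalised library sizes. The median tagwise biological coefficient of variation was 0.235 in kidney and 0.106 in retina.

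Gene lists, 56 in all, covered pathways of diabetic kidney and retina disease, cell types and neighbouring tissues, and were written from general knowledge. Lists with at least 3 genes tested were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. They were tested again with the correlation estimated from the data and with fry. The p-values were adjusted over the lists of a comparison. Counts of list genes are given over all genes tested and again with the p-values adjusted over the list alone.

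This first set held relative log expression normalisation, no expression filter, a sex covariate, limma-trend on log2(TPM + 1), a fit with only the 2 groups compared, DESeq2 1.42.0, and leaving out each library in turn. Sex was read from Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Another 7 settings were chosen after seeing the data: kidney without libraries K861 and K591, a mitochondrial share covariate, that covariate with sex, an adipose list covariate, retina without libraries R915, R942 and R954, a lens list covariate, and protein-coding genes of at least 90% unique sequence only. A further setting was drafted and removed before it was run.

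Unique sequence was the percent of the 31-mers in the transcripts of a gene that occur in no other gene of the annotation. The share of counts given to a copy was computed for 5 gene pairs chosen after values were seen, and the match between the 2 organs of an animal was tested by exact permutation over the 6 knockout animals with both organs. Genes called near Camk2d and Lepr were counted within 5 Mb of the gene, and also within 2 and 10 Mb, with Fisher's exact test. The odds ratio was changed to Fisher's conditional estimate after values were seen, which left the p-values as they were. Windows of 10 Mb with at least 10 protein-coding genes of at least 90% unique sequence were tested with Fisher's exact test for an excess of calls only. Their p-values were adjusted by the Benjamini-Hochberg method over the windows of a comparison. The number of enriched windows was compared with 1000 random draws of genes.

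Genes named in the results follow a rule. The 4 genes of the kinase family and Lepr were considered everywhere. In each comparison of 2 groups, the 8 largest rises and the 8 largest falls were taken among called genes with at least 1 CPM in one group, no overlap between the libraries of the groups, and a gene name that is not a predicted or clone name. Each list with a camera adjusted p under 0.05 added the 4 members of smallest p. The interaction added 8 called genes of smallest p, and a comparison without calls the 3 genes of smallest p. Some of these genes are not reported here. Which of the rest were printed was chosen after values were seen, as were the lists checked for single outlying libraries and other list members that are named. The retina transcripts counted in kidney, Rpl3-ps1, Rps3a and other copies were also chosen after values were seen.

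Power was tested on simulated data. In each comparison 200 genes with a mean of at least 1 CPM over the libraries of the organ were changed 1.5-, 2- or 4-fold. Counts were drawn from negative binomial distributions with the means, library sizes and dispersions of the data. In kidney edgeR recovered 53.7% of genes changed 2-fold and 92.4% of those changed 4-fold in wild-type mice by diabetes, 37.3 and 90.9% in the knockout, 47.8 and 95.5% by genotype in non-diabetic and 50.7 and 89.4% in diabetic mice, and 26.9 and 71.2% in the interaction. In retina the values were 70.1 and 100%, 73.1 and 95.5%, 79.1 and 100%, 79.1 and 97%, and 67.2 and 93.9%. Between 1 and 6 unchanged genes were called in kidney, and 7 to 11 in retina. Camera, with the preset correlation, called the raised list in each of the 10 comparisons and no other list. The simulated counts were drawn from means, library sizes and dispersions alone, so sex, libraries set apart from their group and correlation between genes were not built in. The simulation therefore cannot show how often camera calls unchanged lists when the genes of a list vary together. Nor can it show how many genes are recovered or wrongly called where single libraries stand apart.

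Each comparison was repeated on mixed groupings of the same libraries, with 35 groupings per comparison of 2 groups and 100 random draws for the interaction. Single outlying libraries were sought with Dixon's test in groups of 4 (critical value 0.829), over library measures, genes and list means. Slopes, such as those of log2 fold changes with and without a covariate, were fitted with 95% intervals from 2000 bootstrap draws of genes. These intervals treat genes as independent and leave out the spread between animals. The lens covariate slope was narrowed to genes outside the lens list after the value over all called genes (0.92) was seen. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Blood glucose, kidney function and histology were not analysed here.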

Results

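Kidney and retina RNA was compared between 4 groups of 16-week mice: wild-type or Camk2d knockout, each with Lepr(+/+) (non-diabetic) or Lepr(db/db) (diabetic). The kidney set held 16 libraries, 4 per group. The retina set held 14: 3 wild-type non-diabetic, 4 wild-type diabetic, 4 knockout non-diabetic and 3 knockout diabetic. The 30 libraries came from 21 animals, 9 of which gave both organs, and are named by organ (K or R) and animal number. Levels are means of CPM (counts scaled by normalised library size) ± standard deviation, and fold changes are log2 values ± standard error. Genes were called at an adjusted p under 0.05 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes tested. The p-values and errors cover counting error and the spread between libraries only.

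Camk2d encodes the delta isoform of calcium/calmodulin-dependent kinase II (ENSMUSG00000053819.16, chromosome 3, 126596302 to 126846326, GRCm38). In kidney it lay at 10.3 to 19.8 CPM in the wild-type libraries (n = 8) and 0.0864 to 0.557 CPM in the knockout libraries (n = 8). In retina the wild-type ranges were 285 to 331 CPM (non-diabetic, n = 3) and 316 to 343 CPM (diabetic, n = 4), and the knockout ranges 3.09 to 4.25 (n = 4) and 3.32 to 3.71 (n = 3). The fold in non-diabetic mice was −5.85 ± 0.34 in kidney (adjusted p = 6.33e-08) and −6.35 ± 0.09 in retina (2.51e-16), and in diabetic mice −5.62 ± 0.32 (4.2e-08) and −6.54 ± 0.10 (9.73e-16). Counts per gene do not show which exons were removed. Diabetes did not change Camk2d in wild-type kidney by a called amount (0.44 ± 0.24, adjusted p = 0.237).

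**Figure D1:**
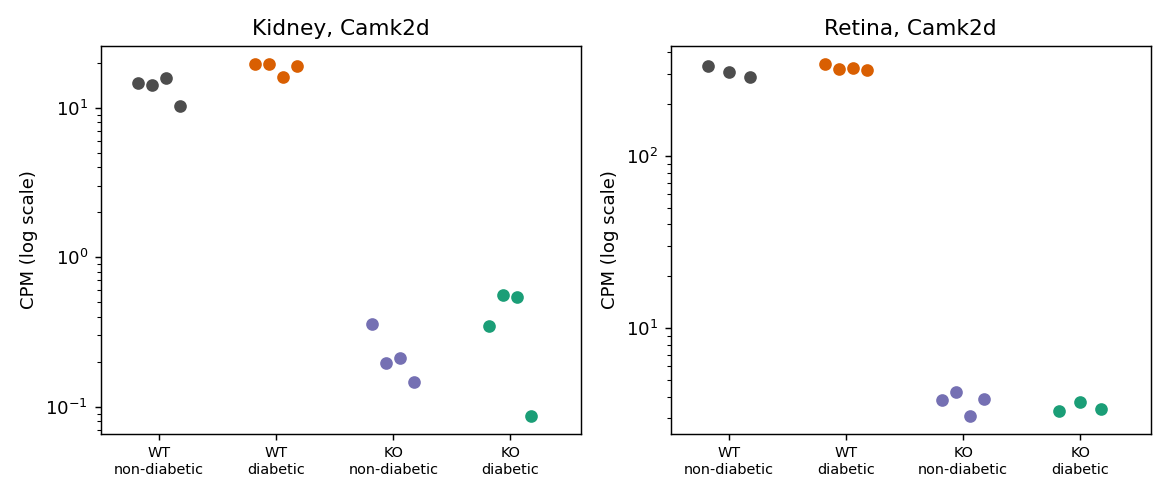
Camk2d in each kidney and retina library, in CPM on a logarithmic axis; n = 3 to 4 libraries per group.

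Of the other 3 isoforms, Camk2b stood at 2.8 to 3.53 CPM in non-diabetic and 3.85 to 6.12 CPM in diabetic knockout kidneys, above each wild-type kidney (0.0437 to 2.25 CPM). It was called in diabetic mice (3.14 ± 0.85, adjusted p = 0.0254) and not in non-diabetic mice (2.87 ± 0.87, 0.342), and the interaction was 0.27 ± 1.21 (0.894). The call ended when library K587 (3.09), K588 (3.06), K591 (3.14), K645 (2.76) or K877 (2.75) was left out, and Camk2b was called in non-diabetic mice without K597 (2.90). Camk2g rose in wild-type diabetic retinas (0.61 ± 0.14, adjusted p = 0.0324): libraries R915, R942 and R954 had 179, 199 and 154 CPM, whereas library R844 had 109 CPM and the non-diabetic wild-type retinas 97 to 109 CPM. That call ended without library R915 (0.55), R942 (0.49), R954 (0.63), R812 (0.64), R819 (0.56) or R852 (0.64), and the Camk2g interaction was −0.43 ± 0.19 (0.454). With all libraries Camk2a was called in no comparison by edgeR. Without K596 it was called between diabetic kidneys (0.92) and for the kidney interaction (1.38), and without R844 for diabetes in wild-type retina (0.44) and between diabetic retinas (−0.42). DESeq2 called the last pair with all libraries (0.37 and −0.35). The leptin receptor gene Lepr (ENSMUSG00000057722.17, chromosome 4, 101717404 to 101815352), which carries the db mutation, fell from 2.56 ± 0.943 to 1.09 ± 0.207 CPM in wild-type diabetic kidneys (−1.24 ± 0.31, adjusted p = 0.024). It was not called in knockout kidneys (−1.53 ± 0.31, 0.0986; interaction −0.29 ± 0.43, 0.659), and the wild-type call ended without library K597 (−1.13), K645 (−1.21), K877 (−1.24) or K834 (−0.96), while Lepr was called in knockout kidneys without K596 (−1.71).

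In wild-type kidney, diabetes raised the genes by which the proximal tubule takes up and makes glucose. G6pc, whose enzyme releases free glucose in the last step of gluconeogenesis, rose from 212 ± 53.6 to 1085 ± 111 CPM (2.35 ± 0.34, adjusted p = 0.00151, n = 4 and 4). The sodium-glucose transporter Slc5a2 rose from 261 ± 66.5 to 612 ± 130 CPM (1.23 ± 0.21, 0.00433), the fructose transporter Slc2a5 from 66.6 ± 20.8 to 204 ± 24.7 CPM (1.61 ± 0.29, 0.00522), and Slc37a4, which carries glucose 6-phosphate to G6pc, by 1.22 ± 0.24 (0.00863). Over the list of 13 genes of glucose reabsorption and gluconeogenesis, 8 rose and none fell (11 and 0 when adjusted over the list alone), and the summed level went from 10000 ± 1140 to 19600 ± 1750 CPM. The camera list test gave an adjusted p of 2.26e-10, and 0.31 with an estimated correlation. Other large rises were Cyp27b1, the renal enzyme that activates vitamin D (4.28 ± 0.69, 0.00349), Hif3a (2.97 ± 0.39, 0.000986) and Zbtb16 (2.92 ± 0.56, 0.0079). Of 1326 genes called, 510 rose and 816 fell, whereas limma on TPM called 142 up and 95 down and an adipose covariate left 70 calls.

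Immune transcripts fell in the same wild-type diabetic kidneys. The chemokines Ccl5 and Cxcl9 went from 2.35 ± 0.70 to 0.27 ± 0.0095 CPM (−3.10 ± 0.40, adjusted p = 0.000919) and from 3.56 ± 1.49 to 0.0927 ± 0.129 CPM (−5.21 ± 0.71, 0.0013). The macrophage receptor gene Csf1r fell from 47 ± 14.7 to 14.8 ± 2.22 CPM (−1.66 ± 0.25, 0.00244), the MHC class II gene H2-Aa from 76.2 ± 27.4 to 27 ± 12.5 CPM (−1.50 ± 0.29, 0.00863), the interferon-induced Gbp2 from 12.4 ± 7.26 to 2.74 ± 0.602 CPM (−2.18 ± 0.37, 0.00435) and the immunoglobulin chain Igkc from 33 ± 17.9 to 4.71 ± 2.83 CPM (−2.81 ± 0.48, 0.00459). Of the interferon response list, 17 of 29 genes fell (25 over the list alone; camera adjusted p = 2.81e-12, and 0.614 with an estimated correlation). Of the lymphocyte list, 11 of 16 fell (15 over the list alone; 2.81e-12, and 0.284 with an estimated correlation), and of the macrophage list 6 of 16 (10 over the list alone; 1.23e-05, and 0.614 with an estimated correlation). Fat transcripts were lower beside them: 6 of 12 adipose genes fell (9 over the list alone; 0.000323, and 0.726 with an estimated correlation), from a summed 746 ± 839 CPM, spread over 114 to 1980 CPM, to 72.7 ± 26.7 CPM.

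Matrix and clock genes changed as well in wild-type kidney. The collagens Col3a1 and Col1a1 fell by 1.25 ± 0.26 (adjusted p = 0.0106) and 1.01 ± 0.22 (0.0143); 5 of 34 fibrosis genes fell and none rose, also over the list alone (camera 0.0433, and 0.826 with an estimated correlation). The Col1a1 call ended without library K597 (−0.90). Tubular injury markers were not called as a list (1 of 19 fell, 2 over the list alone; median −0.21, 0.355). The clock gene Cry2 rose (1.39 ± 0.24, 0.00448), within a list of 18 in which 4 rose and 1 fell (9 and 2 over the list alone; 0.000697, and 0.31 with an estimated correlation). The hour of tissue collection was not given in the sources used here. The number of calls was 460 without library K597, 526 without K877, 561 without K645, 878 without K834 and 2591 without the knockout library K596, which shares the variance estimate.

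In knockout kidney a small set of genes differed with diabetes, and the glucose genes were not among them. Lpl, the lipoprotein lipase, fell from 663 ± 120 to 201 ± 40.4 CPM (−1.72 ± 0.22, adjusted p = 0.0126, n = 4 and 4) and the carboxylesterase Ces2b from 19.4 ± 7.66 to 2.77 ± 1.11 CPM (−2.80 ± 0.40, 0.0162). Rarres2, which encodes the adipokine chemerin, rose from 19.2 ± 1.83 to 48.3 ± 11.8 CPM (1.33 ± 0.21, 0.026), the alarmin Il33 from 4.43 ± 0.862 to 9.26 ± 0.933 CPM (1.06 ± 0.17, 0.0262), and Clca3a1 from 4.97 ± 2.35 to 22.4 ± 4.68 CPM (2.16 ± 0.29, 0.0126), although 59.4% of its sequence is unique. G6pc stood at 254 ± 70.3 and 396 ± 228 CPM (0.64 ± 0.32, 0.369) and Slc5a2 at 267 ± 50.5 and 354 ± 21.1 CPM (0.41 ± 0.20, 0.369). The cholesterol synthesis list was lower (median −0.58; 0 of 22 called over all genes, 10 fell over the list alone; camera 4.04e-09, and 0.668 with an estimated correlation), with Cyp51 at −1.79 ± 0.35 (0.0913).

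Of 14 genes called in knockout kidney, 9 rose and 5 fell. Of these, 9 were also called in wild-type kidney, all in the same direction, where 0.5 would be shared in the same direction if the calls were independent. Over all 18177 genes the 2 diabetes effects had a Pearson correlation of −0.007 and a Spearman correlation of −0.232. Over the 1326 genes called in wild-type mice these were 0.521 and 0.35, and the slope of the knockout on the wild-type effect was 0.21. No gene was called by edgeR without library K588, K591 or K584, and the count was 2 without K582, 5 without K560, 7 without K819, 8 without K844, 9 without K877, 25 without K587 and 2308 without K596; with all libraries 2620 genes had an unadjusted p under 0.05, limma on TPM called 2 and DESeq2 179. By edgeR the count was 1 in a fit of only the 2 groups, 0 with the mitochondrial share as a covariate and 15 with that share and sex. Each named call above therefore ended without K588, K591 or K584, with Lpl at −1.69, −1.72 and −1.61, Clca3a1 at 2.08, 2.05 and 2.10, Ces2b at −2.63, −2.68 and −2.52, Rarres2 at 1.18, 1.31 and 1.34 and Il33 at 1.13, 1.02 and 0.95. Without K582 the calls of Ces2b (−2.76), Rarres2 (1.36) and Il33 (1.11) ended, and without K560 those of Rarres2 (1.26) and Il33 (1.04). Cyp51 was called without K587 (−2.23) or K596 (−1.80).

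Beside Camk2d, 2 further transcripts were nearly absent in non-diabetic knockout kidney. Whether loss of the kinase or a strain variant carried with the knockout line changed them, or the other genes named in this paragraph, was not tested gene by gene. Alox15, a lipoxygenase of macrophages, went from 97.9 ± 58.8 to 0.127 ± 0.0986 CPM (−9.62 ± 0.67, adjusted p = 3.54e-07, n = 4 and 4) and the tetraspanin-like Tm4sf5 from 19.8 ± 8.34 to 0.0723 ± 0.0304 CPM (−8.01 ± 0.49, 9.11e-08). The glyoxalase gene Glo1, whose enzyme detoxifies methylglyoxal, fell from 237 ± 7.68 to 91.1 ± 12.7 CPM (−1.38 ± 0.18, 0.000812), and Plcl2 rose from 2.76 ± 0.936 to 10.6 ± 1.57 CPM (1.94 ± 0.25, 0.000906). Several calls fell on near-identical copies and their levels are uncertain: Hmga1b (7.3% unique) at −7.58 ± 0.54 (4.8e-07) beside Hmga1 (37.9% unique) at 3.69 ± 0.53 (0.00256), and Tpm3-rs7 (21.4% unique) at −8.83 ± 0.38 (2.18e-09). In all, 26 genes rose and 53 fell. Neither the glucose list (camera 0.275) nor the fibrosis list (0.122) was called. Adipose genes were lower (median −2.15; 0 of 12 over all genes, 4 fell over the list alone; camera 1.02e-07, and 0.586 with an estimated correlation). The erythroid list was higher by camera (7 tested, median 1.40; 4.45e-05, and 0.586 with an estimated correlation). Its summed level overlapped between groups, at 32.2 to 703 CPM in wild-type and 421 to 1520 CPM in knockout libraries. Both lists hold markers from outside the nephron. Without library K584 the count of 79 was 51.

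In diabetic kidney, loss of Camk2d went with lower glucose genes and higher immune genes. G6pc was 1085 ± 111 CPM in wild-type and 396 ± 228 CPM in knockout mice (−1.45 ± 0.33, adjusted p = 0.0129, n = 4 and 4), Slc2a5 204 ± 24.7 and 79.2 ± 41 CPM (−1.36 ± 0.28, 0.00963) and Slc37a4 fell by 1.12 ± 0.24 (0.0106). Of 13 genes of glucose reabsorption and gluconeogenesis 12 fell, also over the list alone (camera 9.76e-08, and 0.364 with an estimated correlation), and the summed level was 10800 ± 3030 CPM in the knockout, near the 10300 ± 1420 CPM of non-diabetic knockout kidneys. Glud1, which feeds glutamate into gluconeogenesis, fell from 700 ± 101 to 327 ± 97.2 CPM (−1.10 ± 0.20, 0.0052). Fgg, a fibrinogen chain, fell from 12.4 ± 2.98 to 1.98 ± 0.687 CPM (−2.63 ± 0.31, 0.000199). Alox15 (−4.21 ± 0.68, 0.00265) and Tm4sf5 (−9.60 ± 0.50, 2.16e-08) fell in the same direction as in non-diabetic mice, Alox15 by a smaller fold. The 2 genotype comparisons shared 63 calls, all in the same direction, where 7.5 would be shared in the same direction if independent.

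Macrophage genes were higher in knockout than in wild-type diabetic kidney, 13 of 16 (15 over the list alone; camera adjusted p = 7.13e-10, and 0.364 with an estimated correlation), among them Csf1r (14.8 ± 2.22 to 43.2 ± 16.8 CPM, 1.54 ± 0.25, 0.00255) and Fcer1g (2.02 ± 0.31, 0.00207). In wild-type non-diabetic, wild-type diabetic, knockout non-diabetic and knockout diabetic kidneys, the macrophage list summed to 140, 63.8, 165 and 180 CPM. In the same order, the interferon list summed to 304, 149, 294 and 281 CPM and the lymphocyte list to 63.2, 13.1, 43.1 and 39.8 CPM. For these lists wild-type diabetic kidney was the low group, and knockout diabetic levels lay near those of non-diabetic knockout kidneys. Of the interferon list 19 of 29 rose (22 over the list alone; 1.15e-09, and 0.418 with an estimated correlation), with Rsad2 at 12.7 ± 0.637 and 27.2 ± 4.91 CPM (1.10 ± 0.15, 0.00103). Of the lymphocyte list 11 of 16 rose (15 over the list alone; 7.57e-09, and 0.364 with an estimated correlation), with Cd79a at 3.48 ± 0.51 (0.0015) and Ighm at 2.74 ± 1.12 and 9.75 ± 1.5 CPM (1.83 ± 0.32, 0.00443). The chemokine Cxcl16 rose from 16.6 ± 1.2 to 39.3 ± 7.94 CPM (1.24 ± 0.16, 0.000513), and H2-Aa from 27 ± 12.5 to 83.2 ± 11 CPM (1.62 ± 0.29, 0.00502). Col1a1 rose from 9.06 ± 1.42 to 25.8 ± 7.28 CPM (1.51 ± 0.22, 0.0015) and Pdgfrb by 0.90 ± 0.15 (0.00339), and of 34 fibrosis genes 14 rose and none fell (20 over the list alone; 2.41e-08, and 0.364 with an estimated correlation). Markers of other cells outside the tubule were higher too: the endothelial list summed to 417 ± 49.1 and 621 ± 97.2 CPM (camera 0.000231, and 0.53 with an estimated correlation) and the pericyte list to 144 ± 17.5 and 201 ± 28 CPM (0.0139, and 0.364 with an estimated correlation). Proximal tubule markers were lower, at 23900 ± 2940 and 19000 ± 4650 CPM (0.0139, and 0.577 with an estimated correlation), and blood markers were not called (484 ± 266 and 1330 ± 800 CPM, 0.512). Tubular injury markers were again not called as a list (2 of 19 rose, also over the list alone; median 0.51, 0.113).

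The calls of this comparison were 1939 up and 1634 down, against 173 and 243 by limma on TPM, 2713 and 2900 with a sex covariate and 1167 and 484 in a fit of only the 2 groups. With the mitochondrial share as a covariate 558 were called, 377 up and 181 down. The calls depended on single libraries: 718 without K645, 725 without K597, 763 without K587, 929 without K588, 966 without K877, 1301 without K591 and 7730 without K596. RNA composition differed as well. Mitochondrial transcripts took 31.9, 31.5, 45.4 and 22.2% of the counts of knockout diabetic libraries K587, K588, K591 and K596. In the wild-type diabetic kidneys they took 24.6 to 26.1%, more than in K596 and less than in K587, K588 and K591.

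The interaction asked whether diabetes acted differently in knockout and wild-type kidneys. No gene was called by edgeR (smallest adjusted p 0.0665, 5301 genes at an unadjusted p under 0.05), against 2 by limma on TPM and 1640 by DESeq2. With a sex covariate (2 females and 2 males in each group by their transcripts) edgeR called 1194 (780 up and 414 down), but 0 with sex and mitochondrial share together. It called 24 with no expression filter and 32 among protein-coding genes of at least 90% unique sequence. The smallest p-values belonged to Ms4a14 (3.98 ± 0.57), Bik (2.0 ± 0.33) and the lymphoid factor Ikzf1 (1.77 ± 0.30), all at 0.0665. G6pc, called in wild-type and not in knockout kidney, had an interaction of −1.71 ± 0.45 (0.0755), and Slc5a2 one of −0.82 ± 0.29 (0.107). By list, the lymphocyte genes had an interaction median of 2.23 (0 of 16 over all genes, 14 rose over the list alone; camera 4.59e-09, and 0.583 with an estimated correlation), the interferon genes 1.25 (17 of 29 over the list alone; 1.09e-07, 0.583 with an estimated correlation) and the glucose genes −1.06 (12 of 13 fell over the list alone; 2.01e-07, 0.583 with an estimated correlation). The count was 1 without library K812, 232 without K559 and 5471 without K596. Without K596, Ms4a14 (3.98), Bik (2.20), Ikzf1 (1.80), Cxcl9 (4.59), Lck (2.79) and G6pc (−2.18) were called, and without K559 Ms4a14 (4.10), Bik (1.97), Ikzf1 (1.85), Cxcl9 (5.18) and Lck (3.18). Without K812 the 1 call was Ms4a14 (4.15).

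**Figure D2:**
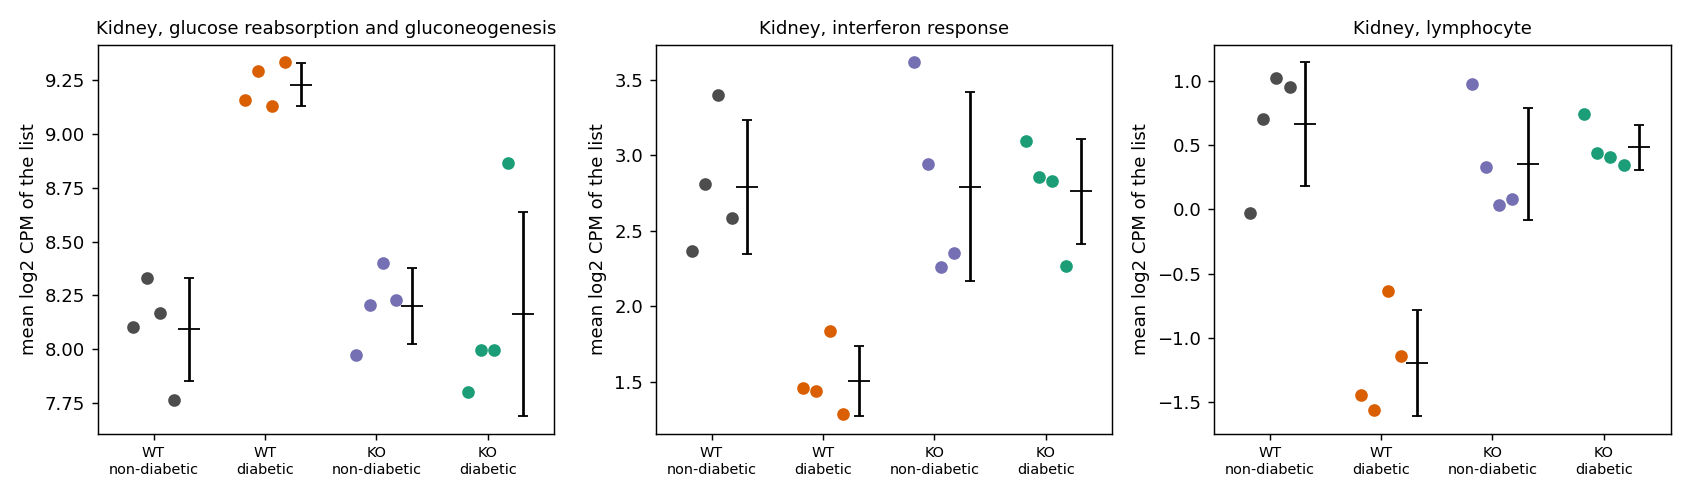
Mean log2 CPM of the glucose, interferon and lymphocyte lists in each kidney library, with the mean ± standard deviation per group; n = 4 libraries per group.

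**Figure D3:**
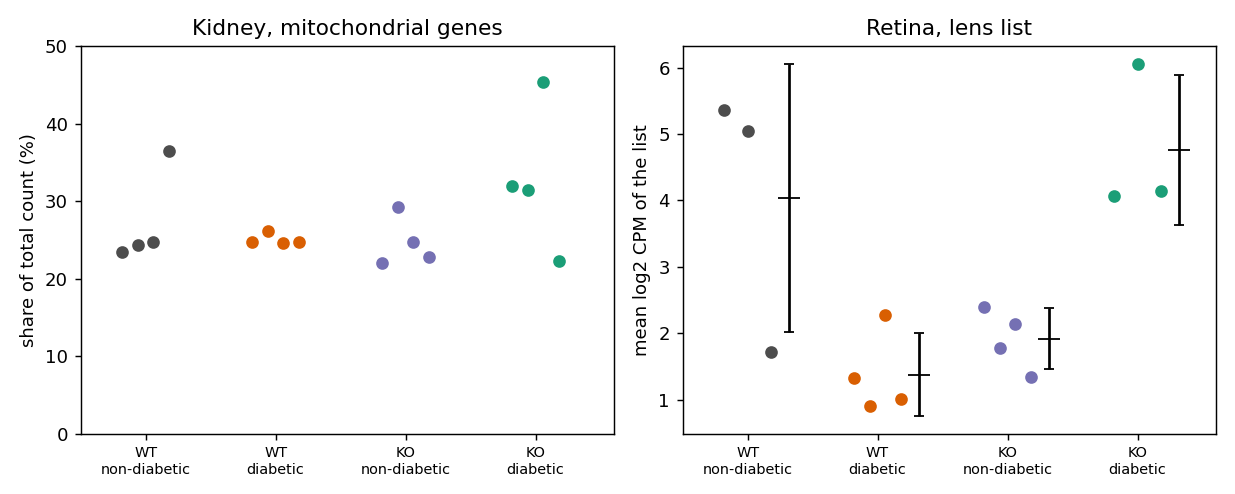
Mitochondrial share of the counts in each kidney library (n = 4 per group), and mean log2 CPM of the lens list in each retina library with the mean ± standard deviation (n = 3 to 4 per group).

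In wild-type diabetic retinas a few cone, endothelial and mitochondrial genes fell by small amounts, and 1 of the 4 diabetic libraries, R844, followed the other 3 with a slope of 0.13 over the genes called without it. Of the cone genes, the phosphodiesterase subunit Pde6h fell from 141 ± 20.8 to 99.1 ± 6.41 CPM (−0.51 ± 0.08, adjusted p = 0.0113, n = 3 and 4) and the transducin subunit Gngt2 from 52.6 ± 3.16 to 39.2 ± 1.89 CPM (−0.43 ± 0.07, 0.00954). Of 11 cone genes 3 fell (7 over the list alone; camera 4.23e-05, and 0.395 with an estimated correlation). The tight junction gene Cldn5 of the vascular barrier fell from 11.7 ± 1.42 to 7.15 ± 0.944 CPM (−0.70 ± 0.14, 0.0191). Of 14 endothelial genes 2 fell (9 over the list alone; 6.12e-06, and 0.0132 with an estimated correlation). The mitochondrial gene mt-Cytb fell from 11200 ± 579 to 8980 ± 485 CPM (−0.32 ± 0.06, 0.0191). Of 13 mitochondrially encoded genes 3 fell (6 over the list alone; 0.000223, and 0.395 with an estimated correlation), and of 32 nuclear respiratory chain genes 3 fell (11 over the list alone; 3.13e-08, and 0.395 with an estimated correlation). The macrophage and microglia list was lower too (3 of 16 fell, 5 over the list alone; 9.7e-06, and 0.395 with an estimated correlation), and the gliosis list was not called (0.167).

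Lens crystallins differed as well between the wild-type retinas. Crygs went from 57.7 ± 45 to 4.42 ± 1.72 CPM (−3.71 ± 0.63, adjusted p = 0.0118), and 12 of 15 lens genes fell (15 over the list alone; camera 8.61e-10, and 0.395 with an estimated correlation). Their summed level ran from 99.8 to 1610 CPM over the 3 non-diabetic libraries. Eno1b, a near-identical copy of Eno1 with 10.8% unique sequence and an uncertain level, was called at 9.15 ± 1.37 (0.00858). Of the 520 genes called, 271 rose and 249 fell, whereas limma on TPM called 200 up and 51 down. A fit of only the 2 groups called 1 gene, outside the 520, and with a lens covariate edgeR called 0 (3997 genes had an unadjusted p under 0.05 without it, and DESeq2 called 1075). The count was 1501 without library R844, 437 without R942, 343 without R560, 332 without R559, 214 without R954, 168 without R852, 145 without R915, 60 without R812 and 4 without R819. The calls of Crygs (−3.19, −3.49) and Cldn5 (−0.64, −0.66) ended without R812 or R819, those of Eno1b (9.10), Pde6h (−0.38) and Gngt2 (−0.38) without R819, and that of mt-Cytb without R915 (−0.29), R812 (−0.28), R819 (−0.36) or R852 (−0.31).

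In knockout retina no gene passed for diabetes. The smallest adjusted p of edgeR was 0.154 (1855 genes at an unadjusted p under 0.05), limma on TPM called 1 gene and DESeq2 86. The photoreceptor gene Rcvrn, which encodes recoverin, stood at −0.28 ± 0.07 (0.218, n = 4 and 3). The 3 smallest p-values were those of Zan (0.52 ± 0.08), Bcap31 (−0.28 ± 0.05) and Gm20422 (4.88 ± 0.78, of uncertain level with 3.9% unique sequence), none of which passed (0.154). As lists, the rod genes were lower (0 of 16 over all genes, 8 fell over the list alone; median −0.16, camera 3.84e-09, and 0.3 with an estimated correlation), as were the mitochondrially encoded genes (0 of 13, 12 over the list alone; −0.27, 5.38e-14, and 0.198 with an estimated correlation). Lens genes were higher (0 of 15, 15 over the list alone; 2.90, 3.37e-17, and 0.3 with an estimated correlation). The count was 1 without library R844, 2 without R587, 5 without R590, 12 without R852 and 15 without R588, with Zan called without R852 (0.52) and Gm20422 without R844 (4.88). Over all 20979 genes the diabetes effects in knockout and wild-type retina had a Pearson correlation of −0.051 and a Spearman correlation of 0.164. Over the 520 genes called in wild-type mice these were −0.434 and 0.164, and no gene was called in both.

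In non-diabetic knockout retinas 2 immediate early genes, a class that neurons switch on with calcium entry and activity, were lower than in wild-type retinas. The phosphatase gene Dusp1 fell from 29.1 ± 6.67 to 14.9 ± 0.645 CPM (−0.96 ± 0.17, adjusted p = 0.00984, n = 3 and 4) and Ier2 by 0.57 ± 0.11 (0.0232). Egr1 did not pass (65.2 ± 47.8 and 19.5 ± 7.45 CPM, −1.74 ± 0.48, 0.107). Of 20 immediate early genes 2 fell (10 over the list alone; median −0.26, camera 0.000108, and 0.353 with an estimated correlation). These genes also respond to tissue handling. Gje1, which encodes a connexin-like protein, rose from 0.426 ± 0.112 to 7.93 ± 1.43 CPM (4.2 ± 0.35, 6.11e-06), the MHC class I gene H2-K2 by 2.72 ± 0.45 (0.00733), and the serine protease gene Prss41 fell from 4.64 ± 0.352 to 0.223 ± 0.0616 CPM (−4.34 ± 0.29, 4.57e-07). The purinergic receptor gene P2rx5 fell from 12.5 ± 3.86 to 2.13 ± 0.412 CPM (−2.55 ± 0.45, 0.01). Lens genes were lower beside them (5 of 15 fell, 15 over the list alone; median −2.74, 1.7e-08, and 0.536 with an estimated correlation).

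The copy genes Hmga1 (3.12 ± 0.08, adjusted p = 2.31e-12) and Hmga1b (−8.86 ± 0.23, 1.97e-12) were called in the same direction as in kidney, and each level is uncertain as their reads are shared. In all, 133 genes rose and 107 fell between non-diabetic knockout and wild-type retinas. The count of 240 was 120 without library R819, 137 without R852, 138 without R812, 140 without R560, 142 without R559 and 373 without R844. The call of Dusp1 ended without R852 (−0.80), that of P2rx5 without R819 (−2.33) and that of Ier2 without R560 (−0.53), R590 (−0.54), R819 (−0.48) or R852 (−0.51), whereas Egr1 was called without R812 (−2.23).

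In diabetic retina, interferon-induced genes were higher in the knockout. Bst2, a restriction factor, rose from 1.17 ± 0.289 to 3.18 ± 0.881 CPM (1.44 ± 0.29, adjusted p = 0.0239, n = 4 and 3) and the RNA sensor Ifih1 by 0.75 ± 0.16 (0.0318). Of 26 interferon genes 4 rose (15 over the list alone; camera 7.58e-09, and 0.446 with an estimated correlation). The list was higher in non-diabetic knockout retinas as well (0 over all genes, 1 over the list alone; median 0.38, 0.000465, and 0.662 with an estimated correlation). Prss41 fell from 4.83 ± 0.465 to 0.193 ± 0.173 CPM (−4.59 ± 0.32, 8.37e-07). Lens genes rose beside them, 14 of 15 (15 over the list alone; 4.54e-15, and 0.446 with an estimated correlation), with Cryba4 from 2.03 ± 0.857 to 31 ± 20.6 CPM (3.93 ± 0.68, 0.0124) and Lgsn at 4.54 ± 0.81 (0.0138). Eno1b was called at −9.0 ± 1.35 (0.00451), with an uncertain level. Of 374 calls 213 rose and 161 fell, against 133 and 47 by limma on TPM and 156 and 71 among protein-coding genes of at least 90% unique sequence. The genotype comparisons of retina shared 75 calls, 71 in the same direction, where 2.2 would be shared in the same direction if independent.

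Without single retina libraries the 374 calls became 1120 (R844), 193 (R954), 140 (R915), 123 (R942), 110 (R588), 100 (R587) and 91 (R591). The calls of Cryba4 (3.24) and Lgsn (3.10) ended without R588, that of Bst2 without R587 (1.19), R588 (1.51), R915 (1.27) or R942 (1.51), and that of Ifih1 without R587 (0.57), R588 (0.83), R591 (0.83), R915 (0.69), R942 (0.73) or R954 (0.69).

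The retina interaction called 26 genes, 24 up and 2 down, 13 of them lens genes, against 71 up and 91 down by DESeq2 and 52 and 53 with no expression filter. The crystallins Cryba4 (6.68 ± 0.93, adjusted p = 0.0196), Crygs (6.42 ± 0.87, 0.0196) and Crybb2 (6.56 ± 0.96, 0.024) gave 3 of the smallest p-values. Of 15 lens genes 13 rose (15 over the list alone; median 6.42, camera 1.42e-24, and 0.254 with an estimated correlation). The lens list summed to 916 ± 761, 80.3 ± 41.8, 142 ± 42.9 and 951 ± 603 CPM in wild-type non-diabetic, wild-type diabetic, knockout non-diabetic and knockout diabetic retinas (n = 3, 4, 4 and 3). Endothelial genes had an interaction median of 0.37 (0 of 14 over all genes; 0.000302, and 0.0404 with an estimated correlation). No gene was called by edgeR without library R559, R560, R582, R812, R819 or R915 (2157 genes had an unadjusted p under 0.05 with all libraries, where limma on TPM called 0 and DESeq2 162), and the count was 1 without R590, 7 without R954, 12 without R942, 17 without R588 and 541 without R844.

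Genes next to the 2 engineered or mutated loci were counted apart, since they stay with a locus through breeding. Within 5 Mb of Camk2d, 9 of 92 genes tested were called between non-diabetic knockout and wild-type retinas (9.78% against 1.1% elsewhere, odds ratio 9.74, Fisher exact p = 1.06e-06), and 3 of 80 in kidney (3.75% against 0.41%, 9.36, exact p = 0.00493). In diabetic mice these were 6 of 92 in retina (odds ratio 3.9, exact p = 0.006) and 23 of 80 in kidney (1.65, exact p = 0.0477). Within 5 Mb of Lepr, 1 of 51 genes was called for diabetes in wild-type kidney (1.96% against 7.3%, exact p = 0.181), 0 of 51 in knockout kidney (exact p = 1) and 1 of 50 in wild-type retina (exact p = 1). The calls between non-diabetic knockout and wild-type retinas also gathered on chromosome 17 at 20 to 30 Mb, with 13 of 137 genes (9.5% against 0.96% elsewhere, adjusted exact p = 5.2e-07). They gathered in 3 further 10 Mb windows on chromosomes 3 and 11 too. Camk2d lies on chromosome 3, and it and its neighbours were not left out of the windows. Together these 4 windows held 34 of 129 calls among protein-coding genes of at least 90% unique sequence (26.4%), and 3.2% of such genes.

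The share of counts given to near-identical copies differed between animals. Rpl3-ps1 took 85.2% of the counts of Rpl3 and its copy in kidney K559 and 88.7% in retina R559 of the same animal, 41.4 and 45.0% in K560 and R560, 40.5 and 41.8% in K591 and R591, and at most 0.8% in K582, K587, K588 and the retinas of the same animals. Tpm3-rs7 took 50.1 to 52.5% of the counts of its pair in wild-type retinas R812, R819, R844 and R852, and at most 0.6% in wild-type diabetic retinas R915, R942 and R954. In kidneys K812, K819 and K844 Tpm3-rs7 took 71.7, 80.4 and 81.6%, so its share also differed between the organs of an animal. In R915, R942 and R954 Eno1b took 50.8, 45.9 and 49.2% of its pair, and at most 0.3% in every other library of either organ. Over the 6 knockout animals with both organs, an exact permutation test of the match between organs gave p = 0.0167 for Rpl3, the smallest that its ties allow, and 0.0389 for Rps3a (0.0835 and 0.0972 when adjusted over 5 pairs). The other 3 pairs could not be tested, as the kidney share of the copy stayed at 0 to 1.3% for Hmga1b, 0.1 to 0.4% for Tpm3-rs7 and 0 to 0.3% for Eno1b in these animals, and ties kept p above 0.05 under any match.

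**Figure D4:**
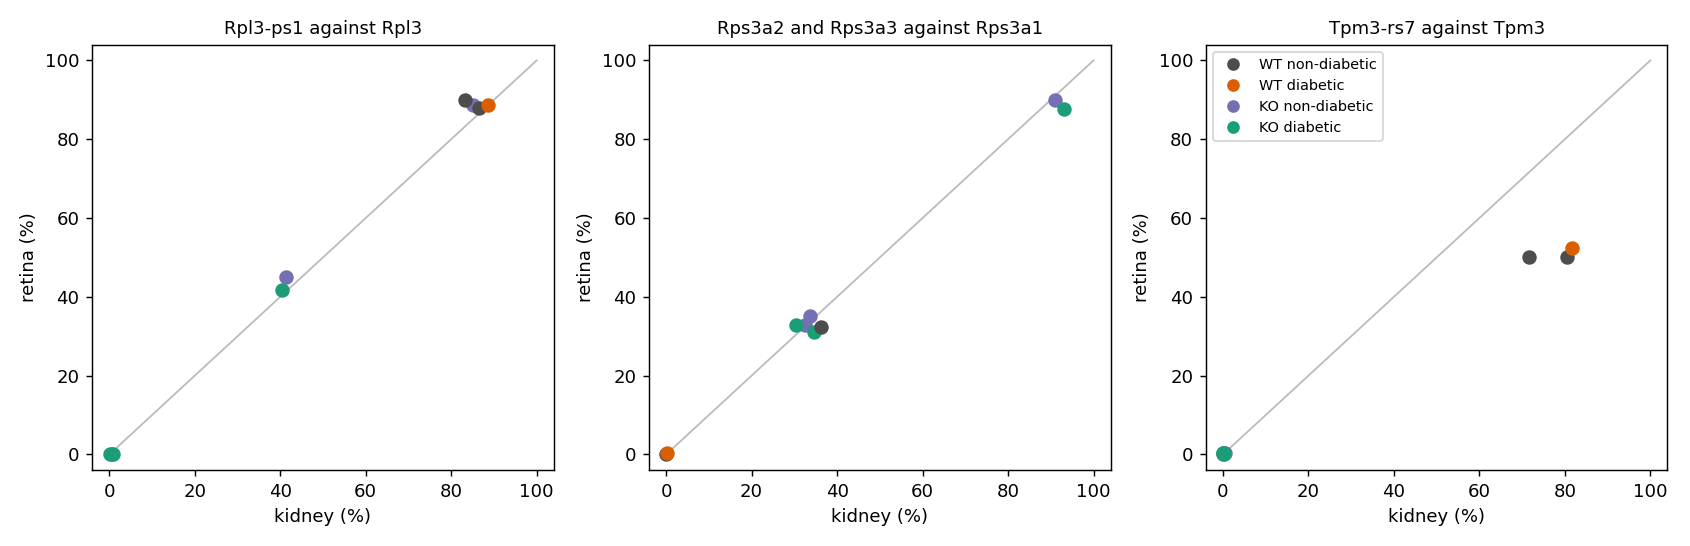
Percent of counts assigned to the named copy within each pair, kidney against retina of the same animal, with the line of equality; n = 9 animals.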

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

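The 6 tests of explanations given here (unique sequence, clustered windows, the slope of library R844, the lens slope, the mitochondrial slope and the slope between diabetic states) were chosen after the result was seen, and the regroupings of libraries were planned. Intervals of the slopes come from draws of genes and leave out the spread between animals.

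Genes called between knockout and wild-type mice clustered on the genome and among gene copies. Among the 240 calls in non-diabetic retina, 61.7% had at least 90% unique sequence (exact 95% interval 55.2 to 67.8), against 72.5% of the genes tested, and in kidney 48.1% (36.7 to 59.6) against 72.8%, so reads shared between near-identical copies cannot be the whole cause. A strain variant carried with the knockout line is a candidate explanation: 4 windows of 10 Mb were enriched in retina, where 1000 random draws of genes gave 2 at most, and 1 window in kidney, which 16 of 1000 draws equalled. Camk2d and its neighbours were not left out of these windows. An effect of the kinase on genes outside these windows stays open, since 26.4% of the 129 calls with unique sequence in retina lay within them. Strain background was not given in the sources used here.

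The wild-type diabetic retinas were of 2 kinds. Library R844 followed the other 3 with a slope of 0.13 (95% interval 0.09 to 0.16) over the 1501 genes called without it, 1086 of them with the same sign. This goes with R915, R942 and R954 carrying other gene copies than the remaining wild-type retinas. The genes were chosen by the other 3 libraries, which lowers the slope. When R915, R942 or R954 was the one left out, the slopes were 1.19, 1.03 and 1.18. Those used 145, 437 and 214 genes chosen with R844 included, against means that include R844, so they are not comparable like for like. With a lens covariate, 0 of the called genes stayed called by edgeR, because the median standard error of those outside the lens list went from 0.12 to 0.17 while the median fold went from 0.59 to 0.54. The slope of their folds with the covariate on those without was 0.98 (0.93 to 1.03), and 507 of 508 had the same sign. This argues against lens tissue as the whole cause for genes outside the lens list. It does not exclude it, since all genes share the error of the fitted lens effect, which the interval leaves out. For the lens genes themselves lens tissue stays open, as a covariate made from them cannot test them, and so does an effect of diabetes that varies between mice, since R844 is labelled diabetic too.

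The knockout minus wild-type difference in diabetic kidney was large. Of its calls, 63 were shared with the 79 calls in non-diabetic kidney, all in the same direction. With the mitochondrial share as a covariate, 549 of the 3573 genes stayed called, the median fold went from 0.92 to 0.73 and its standard error stayed at 0.25, so calls ended because folds shrank. The slope of the folds with the covariate on those without was 0.88 (0.86 to 0.90), all 3573 with the same sign, which argues against the mitochondrial share as the whole cause. Without selection of genes, a line difference present in both diabetic states would give a slope near 1. The slope of the non-diabetic on the diabetic folds was 0.18 (0.11 to 0.25), with 1468 of 3573 genes of the same sign. These genes were chosen by their diabetic folds, which lowers the slope, so the slope alone cannot decide how much is shared. The 1 knockout library set apart from the other 3 (K596), and how strongly diabetic each mouse was, which was not analysed here, stay open.

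In 2 of the 10 comparisons no other grouping had as many calls as the real one, which is a share under 0.05. It is the smallest share that 35 groupings allow, and shares were not adjusted over the 10 comparisons. In wild-type kidney the real grouping by diabetes, with 1326 calls, was the 1 of 35 with as many, and the highest other had 0 (edgeR). Between non-diabetic knockout and wild-type retinas it was 1 of 35, with 240 calls and 16 in the highest other. For the retina interaction 4 of 100 draws had as many as the real 26, the real one included, with 341 in the highest other. These draws exchange genotypes within each diabetic state, so genotype differences add to the spread within their groups, and a share under 0.05 is weak ground against chance here. For 5 others the share was 0.05 or more, so this count did not exclude chance. For diabetes in knockout kidney 4 of 35 had as many as 14, and the highest other (4090) set K587, K588, K591 and K559 against the rest, while another (1666) was exactly the females K587, K588, K559 and K560 against the males. Between non-diabetic knockout and wild-type kidneys 2 of 35 had as many as 79, and the 1 other (1638) was exactly the females K559, K560, K819 and K834 against the males. That grouping measures sex, which the regroupings left out of the fit, so it says little about chance, and a fit with sex gave 107 for genotype. Between diabetic knockout and wild-type kidneys 2 of 35 had as many as 3573, and the highest other (6706) exchanged K596 for K844. For diabetes in wild-type retina 2 of 35 had as many as 520, and the highest other (1280) set R915, R942 and R954 against the rest. Between diabetic knockout and wild-type retinas 2 of 35 had as many as 374, and the highest other (1004) set the same 3 libraries against the rest. For the kidney interaction and diabetes in knockout retina the real edgeR count was 0 (5301 and 1855 genes at an unadjusted p under 0.05, and 1640 and 86 calls by DESeq2), which every grouping equals, so the 100 draws (highest 7607) and 35 groupings (highest 8) test nothing about chance. Where another grouping called several times the real count, it points to a structure of the samples, such as sex in non-diabetic and in knockout kidney and, in the latter, K587, K588, K591 and K559 against the rest.

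Single libraries stood far from the other 3 of their group in 34 of 240 groups of 4 checked, where chance gives about 1 in 20. In wild-type non-diabetic kidney, K861 had a mitochondrial share of 36.4% (others 23.46 to 24.74), 39.13% of counts in its top 10 genes (26.81 to 27.2), Camk2g at 25.2 CPM (19.1 to 20.1), an Eno1b share of 0.2% (0.1) and a mitochondrial genome list mean of 14.31 (13.23 to 13.3). Library K812 had Camk2b at 1.01 CPM (0.164 to 0.28), Cidea at 130 CPM (1.18 to 9.02) and an Rps3a2 and Rps3a3 share of 36.3% (0 to 0.2), and K834 had H2-Aa at 117 CPM (60.4 to 66.5). In wild-type diabetic kidney, K645 had a mitochondrial share of 26.14% (24.55 to 24.77), Camk2a at 0.519 CPM (0.704 to 0.742), Cidea at 2.31 CPM (0.0437 to 0.0898), Clca3a1 at 17 CPM (25.3 to 27) and an Hmga1b share of 44.4% (85.8 to 91.1). Library K597 had Camk2b at 2.25 CPM (0.0437 to 0.0472) and a Tpm3-rs7 share of 37.5% (79.1 to 82.7), and K844 had H2-Aa at 45.8 CPM (19.8 to 21.8) and Igkc at 8.91 CPM (2.69 to 3.68). In knockout non-diabetic kidney, K560 had Cyp27b1 at 30.1 CPM (2.99 to 6.41), and K559 had Cidea at 2.85 CPM (0.0491 to 0.16) and a macrophage list mean of 3.07 (2.345 to 2.413). In knockout diabetic kidney, K587 had Slc22a7 at 168 CPM (1.82 to 7.13) and Cidea at 0.259 CPM (0 to 0.0432), K588 a Tpm3-rs7 share of 0.2% (0.1), and K596 a cholesterol synthesis list mean of 4.937 (4.139 to 4.173). The Tpm3-rs7 share of K588 rests on 3 counts and was rounded before the test, so it is no clear outlier.

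In wild-type diabetic retina, R942 had Crygs at 6.97 CPM (others 3.26 to 3.81), R915 an MHC class II list mean of −0.349 (−0.184 to −0.153) and R954 a clock list mean of 6.141 (6.244 to 6.257). Library R844 had an Rps3a2 and Rps3a3 share of 0.4% (87.3 to 90.1), a Tpm3-rs7 share of 52.5% (0.2 to 0.6) and an Eno1b share of 0.2% (45.9 to 50.8). In knockout non-diabetic retina, R559 had an Rps3a2 and Rps3a3 share of 89.9% (32.4 to 35.2), R590 an MHC class II list mean of 0.544 (−0.049 to 0.027) and R582 a lymphocyte list mean of 0.269 (0.529 to 0.58).

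By the interaction term of the retinas lens genes were called, among them Crygs (6.42), Cryba4 (6.68), Cryba2 (6.16), Cryba1 (6.04), Crybb2 (6.56), Crybb1 (5.95), Lgsn (7.43) and Cryaa (5.84). The lens list summed to 99.8 to 1610 CPM among the 3 wild-type non-diabetic retinas alone, and no interaction was called by edgeR with a lens covariate (2157 genes at an unadjusted p under 0.05 without it, 162 called by DESeq2 and 0 by limma on TPM), so lens tissue left on some retinas stays open for these genes. By the camera test of the interaction the effect of diabetes differed in kidney for 16 lists, with medians of −0.42 (fatty acid oxidation), −0.71 (cholesterol synthesis), 0.65 (fibrosis), 0.66 (inflammation), 1.25 (interferon response), 1.19 (MHC class II), −0.34 (insulin and leptin signalling), 0.69 (mitochondrial genome), −0.62 (clock), 1.14 (macrophage), 2.23 (lymphocyte), 0.65 (endothelium), 1.14 (pericyte), −1.06 (glucose reabsorption and gluconeogenesis), −0.47 (proximal tubule) and −0.67 (distal convoluted tubule). In retina it differed for 7 lists, with medians of 0.21 (cholesterol synthesis), 0.21 (immediate early genes), 0.36 (macrophage), 0.37 (endothelium), −0.2 (rod), 0.29 (cone) and 6.42 (lens). With an estimated correlation, 1 of these 23 lists, the retinal endothelium, kept an adjusted p under 0.05.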

How the results depend on the processing

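The settings chosen after seeing the data, 7 in all, were kidney without K861 and K591, the mitochondrial, mitochondrial with sex, adipose and lens covariates, retina without R915, R942 and R954, and protein-coding genes of at least 90% unique sequence; the others were planned. Counts of calls are given in the order diabetes in wild-type, diabetes in knockout, genotype in non-diabetic, genotype in diabetic mice and interaction (main counts 1326, 14, 79, 3573 and 0 in kidney, and 520, 0, 240, 374 and 26 in retina), and where not stated otherwise the cause was not tested. No paired analysis was possible because no animal is in 2 groups of one organ.

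Relative log expression normalisation kept every count within 1.5 times the main one. With no expression filter, which tests more genes, the kidney counts for genotype in diabetic mice and the interaction were 2348 and 24, and all 5 retina counts rose to 796, 38, 401, 599 and 105. A sex covariate raised the kidney counts to 2554 and 37 for diabetes, 107 and 5613 for genotype and 1194 for the interaction. Limma on TPM gave 237, 2, 52, 416 and 2 in kidney and 251, 1, 158, 180 and 0 in retina (by edgeR 26 in the last, with 2157 at an unadjusted p under 0.05, and 162 by DESeq2). Fits with only the 2 groups compared, which estimate the spread from fewer libraries, gave 1 for diabetes in knockout kidney and 1651 for genotype in diabetic kidney, and 1, 16, 408 and 61 for the 4 retina comparisons. DESeq2 gave 2498, 179, 173 and 1640 in kidney (all but genotype in diabetic mice) and 1075, 86, 506, 703 and 162 in retina. On simulated data DESeq2 called 23 unchanged genes in kidney and 18 in retina for genotype in diabetic mice, and edgeR 5 and 11.

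Protein-coding genes of at least 90% unique sequence, which are fewer, gave 26 for genotype in non-diabetic kidney, 32 for the kidney interaction, and 132, 227 and 15 for the 2 genotype comparisons and the interaction in retina. Without K861 and K591 the kidney counts for diabetes in knockout and genotype in diabetic mice were 4 and 1898. With a mitochondrial covariate these were 0 (edgeR; 2620 genes at an unadjusted p under 0.05 and 14 calls without the covariate, 179 by DESeq2) and 558, and with mitochondrial share and sex 3652 for diabetes in wild-type, 130 for genotype in non-diabetic and 2130 for genotype in diabetic mice. An adipose covariate gave 70 for diabetes in wild-type kidney and 47 for genotype in non-diabetic kidney. Of the 1326 wild-type calls 1321 kept their sign with it, with a slope of 0.84 (95% interval 0.80 to 0.88), the median fold went from 1.27 to 1.09 and the standard error from 0.29 to 0.38, so calls ended by both. Without R915, R942 and R954, where 1 wild-type diabetic library is left and is assumed to vary like the other groups, the retina counts were 21, 1, 431, 128 and 1. A lens covariate gave 0 for diabetes in wild-type retina (edgeR; 3997 genes at an unadjusted p under 0.05 and 520 calls without the covariate, 1075 by DESeq2), 73 and 23 for the genotype comparisons and 0 for the interaction.

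Leaving out 1 library at a time, the kidney counts ran from 460 to 2591, 0 to 2308, 51 to 84, 718 to 7730 and 0 to 5471, and the retina counts from 4 to 1501, 0 to 15, 120 to 373, 91 to 1120 and 0 to 541. In kidney the highest counts came without K596, and in retina without R844 except for diabetes in the knockout (without R588).

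The list tests called 15, 11, 8, 14 and 16 lists in kidney and 10, 7, 14, 11 and 7 in retina with the preset correlation. With an estimated correlation these were 0 in each kidney comparison and 1, 0, 0, 0 and 1 in retina, and with fry 6, 0, 2, 17 and 6 in kidney and 10, 2, 4, 3 and 2 in retina. The correlation of the diabetes effect between genotypes was 0.521 in kidney and −0.434 in retina over genes called in wild-type mice, against −0.007 and −0.051 over all genes. The odds ratio near Lepr in wild-type kidney passed within 10 Mb (0.333), and those near Camk2d in diabetic mice did not pass within 10 Mb in kidney (1.12) or within 2 Mb in retina (3.82).

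Of the values of single genes in the text and their companions, DESeq2 kept 176 of 198 in direction and side of the threshold, normalisation 207 of 208, no filter 194 of 208, sex 195 of 208, limma 131 of 208, fits of 2 groups 129 of 178, unique genes 158 of 164, the mitochondrial covariate 101 of 117 and with sex 111 of 117, the adipose covariate 84 of 117, the lens covariate 38 of 91, leaving out the 3 retinas 46 of 90, and leaving out 1 library 2695 of 3143. Without K861 and K591, 12 of 117 lost the threshold. Direction turned for 3 values that were called with or without the setting, and others called in neither changed sign, such as the kidney Camk2b interaction (0.27, and −0.63 without K812). Camk2b for diabetes in wild-type kidney was 0.47 (adjusted p = 0.75, edgeR) and ran from −3.08 without K597 (0.0311), which held 2.25 CPM, to 1.37 without K812. Cidea in the same comparison was 0.50 (0.79) with the adipose covariate, of whose list it is a member. Bfsp1 for genotype in diabetic retina was −0.04 (0.986) with the lens covariate, of whose list it is a member. At the depth of these libraries, 53.7% of genes of at least 1 CPM changed 2-fold by diabetes were recovered in simulated wild-type kidney, and 70.1% in retina. Libraries set apart from their group were not simulated.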

Other observations

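The match of gene copies between the 2 organs of an animal was tested on pairs chosen after the result was seen.

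Sex read from transcripts was 2 females and 2 males in each kidney group. In retina the wild-type diabetic group held R844 and R942 as females and R915 and R954 as males, so the 3 libraries that stood apart were of both sexes. In the principal component analysis of kidney the first component held 32.4% of the variance, with K587, K588 and K591 at 65.7, 55.6 and 36.4 and K596 at −32.2, and with the wild-type diabetic libraries K597, K645, K877 and K844 at −64, −65.2, −55.5 and −20.9. In retina it held 25.9%, with R915, R942 and R954 at 50.4, 51.9 and 47.6 and R844 at −7.3, near the wild-type non-diabetic libraries (−14 to −7.8).

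Counts of retina transcripts in knockout diabetic kidneys K587, K588, K591 and K596 were 0, 18, 19 and 17 for Prph2, 1, 12, 11 and 5 for Pde6b and 0, 9, 3 and 6 for Snap25; K819, a wild-type non-diabetic kidney, held 1, 7 and 2.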
